A study of Rattus norvegicus with 4 samples.

How the data were processed

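Gene expression was measured in 4 rat cell samples on 4 Agilent 1-colour (Cy3) arrays, with 1 array per group. The groups were neural stem cells from the adult hippocampus, neural stem cells from the olfactory bulb, and neurons derived from each of these stem cell cultures. Per the labels, each array held total RNA pooled from 3 independent experiments, so an array averages over those experiments and gives no spread between them.

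The deposited files hold the fluorescence intensity of each spot, the signal of the labelled RNA bound to a probe. Per the file headers and the submitters' processing notes, the arrays were read with Agilent Feature Extraction 10.5.1.1, which subtracted background and removed spatial trends within each array, and no normalization between arrays was recorded. The authors' table for the whole series held the same intensity values as the scanner output (largest difference 0), so using it in place of the scanner files could move no value. Per the file headers, both stem cell arrays lay on 1 slide and both neuron arrays on the other. Slide and cell state therefore cannot be told apart, while each comparison of hippocampus with olfactory bulb lies within a slide.

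Here the processed signal was converted to log2 and each array's 75th percentile was subtracted. Of 41012 non-control probes, 254 were left out because the scanner software marked a spot as an outlier on an array, and spots of the same probe were averaged. No spot was saturated. Probe accessions were matched without version numbers to a reference gene table of the rat assembly GRCr8, used for names only, because the headers name rn4 as the build of the probe design. Of the 40758 probes kept, 10783 matched 1 gene symbol, 0 matched several and 29975 matched none, which gave 8927 genes. Sox2 and Wnt3 had no named probe. For the 1597 genes with 2 or more probes, the probe with the highest mean over the 4 arrays was used. Probes of a gene differed with a median SD between 0.0915 and 0.137 log2 units over the 4 comparisons, and 1 gene in 1 comparison had probes at 2-fold or more in opposite directions.

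A gene entered a comparison when it was well above background on at least 1 of the 2 arrays. Where 1 side was not well above background, its level was replaced by the lowest signal among probes well above background on that array, or by its own signal if higher, and the difference is a bound. Such differences are given as "at least". With 1 array per group no single comparison could be tested and no difference has a replicate check; the only test was the additive limma fit over all 4 arrays. Genes were called at a difference of 1 log2 unit (2-fold) or more. A difference between the 2 state changes was called at 2 log2 units (4-fold) or more, among genes well above background on all 4 arrays. The spread of log2 signal among spots of a probe printed 10 times had a median SD of 0.092, 0.084, 0.060 and 0.070 on the hippocampal stem cell, olfactory bulb stem cell, hippocampal neuron and olfactory bulb neuron arrays. This is the noise of spots, not of cultures.

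For 33 gene lists, the median log2 difference was set among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart when it lies in the lowest or highest 2.5% of these random lists, which describes these 4 arrays only. Subtracting a constant from an array cannot change this position. Of 32 lists with at least 3 measured genes, chance would put 1.6 apart per comparison if genes varied independently. The random lists hold unrelated genes, while the fixed lists hold related genes and share some members. Genes that vary together between pools would put more lists apart, so 1.6 is a lower guide.

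The comparisons, thresholds, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes per direction with the largest smaller-of-2 difference over both sources or both states, up to 4 more per direction with bounds in both comparisons, 6 per direction by the difference of changes, up to 4 members of each list described, and 13 genes of interest. Which lists were described at length, and which of the members allowed by the rule were named, was decided after their values were seen; members that went opposite ways, such as Atf3, were added at that stage. Further genes outside the rule are named as such, and some genes that the rule takes are not reported here. Genes with a near-identical copy, among them Ins1 and Ins2, Oas1a and Oas1i, Gsta1, Gzmc and Ifi27l2b, are uncertain, since a probe may bind the RNA of the copy.

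The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, only genes well above background on all 4 arrays, no filter on dim probes, the mean over a gene's probes, the authors' table, random lists not matched on expression, and a limma fit. Normexp was planned on mean spot signals, but median spot signals were used, because these were the columns at hand. The limma fit had cell state and cell source as additive terms over the 4 arrays, with Benjamini-Hochberg adjustment. It took the 7112 genes well above background on any array and used their signals as measured, without replacing dim values by the lowest signal. Its 1 residual degree of freedom is the interaction, so it treats any real interaction as noise. Scaling to the Agilent spike-in RNAs (7 probes) and centring each comparison on its median gene were added after the data were seen. On the olfactory bulb neuron array the spike-in fit had an R2 of 0.965 and a slope of 1.09, and the lowest signal well above background was 8.52. The hippocampal stem cell, olfactory bulb stem cell and hippocampal neuron arrays had R2 of 0.997, slopes of 1.03, 1.00 and 1.01, and lowest signals of 11.4, 13.1 and 15.6. How far this moved values of that neuron array was not tested.

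The steps were tested on simulated data with spot noise only, which leaves out the variation between cultures. In a step of 8927 genes, planted differences of 1.5 log2 units or more were called for 94.7% of 150 genes in both comparisons of neurons with stem cells and in the comparison of neurons between sources, and for 95.3% in that of stem cells between sources. No unchanged gene was called. Of 200 random lists without a planted change, 4.0% or 4.5% stood apart, by comparison. For the limma fit on 7112 genes, a first simulation in which all changed genes differed by 2 log2 units recovered 0% of them. A second, designed after that result with differences of 2, 4 or 8, recovered 10%, 92% and 100%.

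Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.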

Results

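Expression was compared between neural stem cells and the neurons derived from them, each from the adult rat hippocampus and the olfactory bulb, in a series whose title names insulin biosynthesis. Each of the 4 groups was measured on 1 array. Of the probes, 60.2% were well above background on the hippocampal stem cell array, 63.8% on the olfactory bulb stem cell array, 66.6% on the hippocampal neuron array and 74.0% on the olfactory bulb neuron array. The number of arrays limits the precision of every value. Differences below are log2 values, with the hippocampal value before the olfactory bulb value, and the stem cell value before the neuron value, unless stated otherwise.

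The first comparison asked how neurons differed from stem cells in each source. Genes of connective tissue, extracellular matrix and astrocytes were much higher on the arrays labelled neurons, while genes of the cell cycle, neuroblasts and cholesterol synthesis were lower. Mgp, a matrix protein that inhibits calcification, was higher by 12.65 and 13.35, and the collagen gene Col1a2 by 11.75 and 11.23. B3gat2, a glucuronyltransferase gene, was lower by 4.58 and 8.08. Of 6651 genes compared in hippocampal cells, 1449 were higher and 1786 lower by 2-fold or more. Of 7018 in olfactory bulb cells, 1884 were higher and 1402 lower. Both sources shared 1208 higher and 1104 lower genes among 6559, where independent lists would share 386.7 and 369.4, and 9 and 15 genes differed in opposite directions. Across 5495 genes well above background on all arrays, the changes in the 2 sources had a Pearson r of 0.866, and genes are not independent replicates. Both comparisons set the same neuron slide against the same stem cell slide, so a difference between the slides would raise the overlap and this r.

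All 15 measured pericyte, fibroblast and smooth muscle markers were higher in both sources, with list medians of 5.22 and 7.29. They included Col3a1 (at least 12.65 and 13.87), the small proteoglycan Dcn (at least 8.07 and 11.03) and the growth factor receptor Pdgfrb (at least 8.68 and 8.41). Among 15 extracellular matrix and integrin genes, 11 were higher and 1 lower in both sources, with medians of 2.86 and 4.88. Spp1, which encodes osteopontin, was higher by at least 10.15 and 9.22, and the fibronectin gene Fn1 by 8.31 and 8.04. Other genes with large differences were the matrix genes Pcolce (10.12 and 10.29), Bgn (9.44 and 8.96) and Htra1 (8.18 and 8.21), Loxl1 (at least 11.84 and 12.29), the matrix protease Mmp14 (at least 11.26 and 12.67) and Srpx (8.17 and 9.68). Ppic, Tpm2, Apeh, Hsd11b1 and Itm2a were also among the 12 leading higher genes, and the hormone gene Retn was higher by at least 11.56 and 14.09.

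Astrocyte and immune markers were higher as well. Of 17 astrocyte markers, 12 were higher in both sources, with medians of 2.94 and 4.98. Gfap, an intermediate filament of astrocytes, was higher by at least 3.69 and 4.98, the gap junction genes Gja1 by 9.88 and 9.86 and Gjb6 by at least 6.67 and 9.32, and Sparcl1 by at least 9.71 in hippocampal cells and by 10.47 in olfactory bulb cells. Of 13 microglia and macrophage markers, 9 were higher and 0 lower in both sources, with medians of 2.18 and 3.31, led by Cd14 (at least 7.56 and 6.74) and the complement gene C1qa (at least 3.88 and 5.99). Interferon and antigen presentation genes had medians of 1.45 and 1.74, and 10 of 17 were higher in both sources, among them Bst2 (5.32 and 6.56) and Irf7 (4.65 and 6.14). Ependymal and cilia genes had medians of 2.80 and 2.94, with 5 of 8 higher in both sources, such as Cd24 (3.46 and 3.80) and Tekt2 (at least 4.25 and 4.54). Retinoic acid genes had medians of 1.52 and 2.67, with 9 of 16 higher in both sources. Tgm2, a transglutaminase, was higher by at least 8.25 and 9.83, and Aldh1a2, which makes retinoic acid, by at least 5.71 and 9.42.

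The endothelial list stood apart in hippocampal cells, with medians of 2.31 and 0.82 (percentile 75.9 in olfactory bulb cells); Eng was higher by at least 6.86 and 7.92 and Emcn by at least 7.74 and 6.49. The BMP and TGF-beta list likewise stood apart in hippocampal cells (1.16) and lay at percentile 96.8 in olfactory bulb cells (1.24). FGF and MAPK feedback genes had medians of 0.69 and 0.47 (percentile 92.7 in olfactory bulb cells). Olfactory ensheathing and Schwann cell markers had medians of 0.80 and 1.17, at percentiles 98.5 and 97.4. These differences between the sources were not tested.

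Of 20 cell cycle genes, 16 were lower and 1 was higher in both sources, and the list medians were -2.67 and -2.38. The replication gene Mcm7 was lower by 3.87 and 3.94, the mitotic genes Birc5 by 3.31 and 3.23 and Ccnb1 by 3.33 and 3.14, while the cyclin gene Ccnd2 was higher by 4.58 and 4.90. Cell cycle inhibitors and p53 targets had medians of 0.22 and 0.96 and stood apart upwards, with 7 of 16 higher and 2 lower in both sources. Their medians turned negative under median scaling in hippocampal cells and under spike-in scaling in olfactory bulb cells. Cdkn1a, which encodes the inhibitor p21, was higher by 4.03 and 4.23, and Gadd45a by 5.56 and 5.10. All 20 cholesterol synthesis genes were lower in hippocampal cells and 17 in olfactory bulb cells, with medians of -2.40 and -1.83; Mvd was lower by 3.15 and 2.15 and Mvk by 2.95 and 2.25. Stress and unfolded protein response genes had medians of -1.43 and -0.81 (percentile 3.58 in olfactory bulb cells). Asns was lower by 2.95 and 2.41, while the small heat shock gene Hspb1 was higher by 8.08 in olfactory bulb cells and also higher in hippocampal cells. Atf3, a stress-induced transcription factor gene, was lower by 2.53 in hippocampal cells and higher by 3.15 in olfactory bulb cells.

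Neuronal genes did not form 1 direction. Of 14 proneural and neuroblast genes, 9 were lower and 1 was higher in both sources, with medians of -2.29 and -2.74. Dlx5 was lower by 3.46 and 7.05, Crmp1 by 3.87 and 5.37, Elavl3 by 2.47 and 6.35, and Tubb3, a tubulin of young neurons, by 2.73 and 3.08, while Stmn2 was higher by at least 5.83 and 5.01. Dcx, a marker of migrating neuroblasts, differed by 0.23 in hippocampal cells and was lower by 2.74 in olfactory bulb cells. Mature neuron and synapse genes had medians of -0.53 in both sources (percentiles 5.99 and 0.21), with 9 of 29 lower and 5 higher in both. The tau gene Mapt was lower by 3.62 and 6.44, Uchl1 by 3.56 and 4.26 and the neurofilament gene Ina by 3.01 and 4.71. Neural stem and progenitor markers had medians of -0.56 and -0.78 (percentiles 35.8 and 1.72). Other leading lower genes were Bik, Coro1a, Hrk, Scrg1, Nup210, Lypd1, Add2 and Nell2, together with Plppr1, Gzmc, Dmrt1 and Ptpro, which were not well above background on either neuron array.

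**Figure D1:**
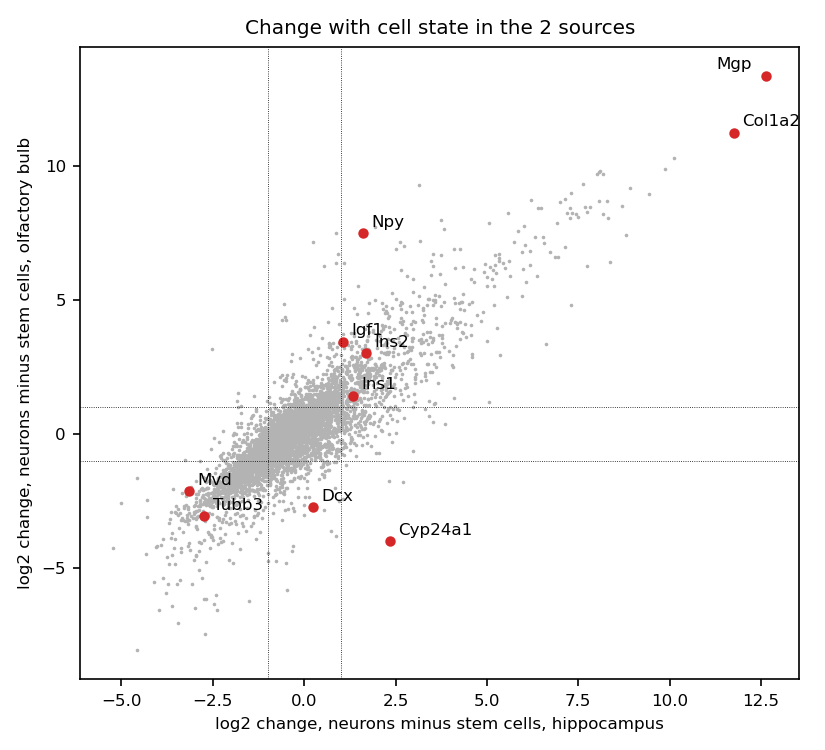
Each point is a gene well above background on all 4 arrays, with the log2 difference of neurons minus stem cells in hippocampal cells on the horizontal axis and in olfactory bulb cells on the vertical axis; dotted lines mark 1 log2 unit (2-fold). Mgp and Col1a2 lie at the upper right, and Cyp24a1 lies off the diagonal at 2.34 and -4.01.

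The 2 rat insulin genes were higher on the arrays labelled neurons in both sources. These arrays also carried stromal and astrocyte markers and lay on another slide, so the rise cannot be assigned to neurons. Ins1 was higher by 2.51-fold and 2.68-fold (log2 1.33 and 1.42), and Ins2 by 3.23-fold and 7.98-fold. On the stem cell arrays, Ins1 was at 7.35 and 12.6 times the lowest signal that counted as well above background. Its signals of 84.0 and 163.9 lay above the median probe signals of 34.8 and 59.2 on these arrays. The signal of Ins2 was low there, at 2.13 and 1.79 times that lowest signal. Every value stayed positive under other processing and Ins2 in olfactory bulb cells stayed at 1.45 or more, but the other calls of 2-fold were lost under at least 1 alternative. Ins1 came to 0.80 in hippocampal cells with normexp, to 0.87 and 0.88 with median scaling and to 0.39 in olfactory bulb cells with spike-in scaling. Ins2 came to 0.46 in hippocampal cells with normexp, whose offset of 50 pulls differences of dim genes towards 0 by construction. Of the insulin and beta cell list, 9 of 20 genes were higher and 5 lower in both sources. Its medians of 0.02 and 0.20 did not stand apart (percentiles 32.7 and 14.3). Cpe, a prohormone-processing carboxypeptidase, was higher by at least 10.11 in hippocampal cells and by 9.30 in olfactory bulb cells. The granin gene Scg2 was higher by 6.76 in hippocampal cells and by at least 4.82 in olfactory bulb cells, and the somatostatin gene Sst by at least 5.42 and 1.88. The transcription factor gene Isl1 was lower by 2.82 in hippocampal cells and by at least 5.56 in olfactory bulb cells.

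Of the transcription factors that act on insulin genes, Pax6 differed by -0.61 and was lower by 1.54 in olfactory bulb cells. Neurod1 was lower by at least 1.57 in olfactory bulb cells and was not well above background on either hippocampal array. Pdx1 was lower by at least 0.65 in hippocampal cells and differed by 0.17 in olfactory bulb cells. Insulin and IGF signalling genes had medians of -0.24 and 0.53 (percentiles 66.5 and 89.2), with 7 of 17 higher and 2 lower in both sources. Igfbp2 was higher by 4.11 and 6.89, Igfbp5 by at least 4.54 and 6.20, and Igfbp4 differed by -0.57 and 0.29. Igf1 was higher by 1.07 and 3.43 on its brightest probe, but its 4 probes ranged from -0.76 to 1.07 in hippocampal cells and from 0.49 to 3.43 in olfactory bulb cells. The myelin gene Mbp differed by -0.27 and was lower by 1.21 in olfactory bulb cells.

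**Figure D2:**
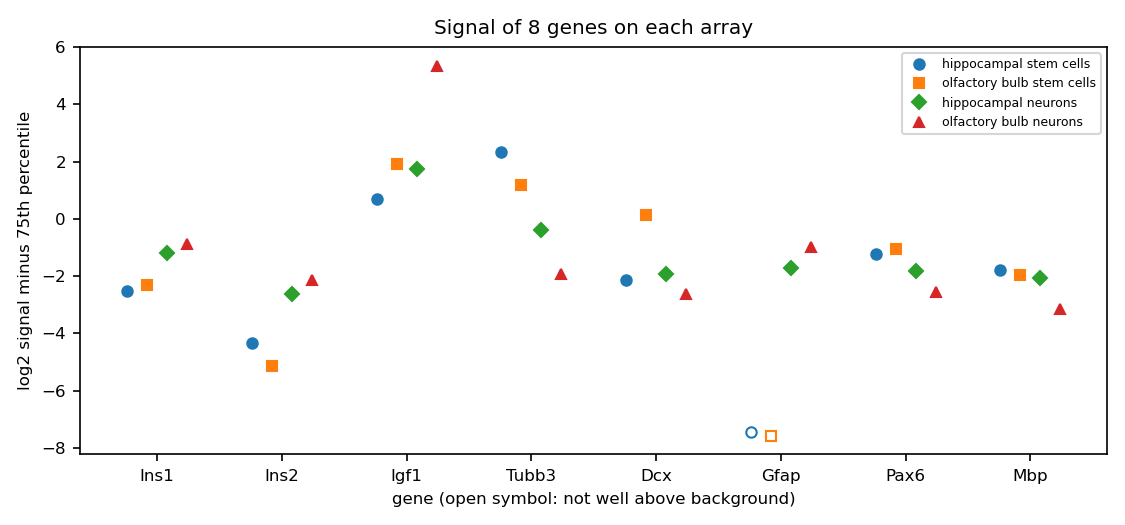
Log2 signal of 8 genes relative to the 75th percentile of each array, 1 symbol per array; open symbols were not well above background. Ins1 and Ins2 lie higher on both neuron arrays than on the stem cell arrays, and Tubb3 lies lower.

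The balance of the state comparison depended on the scaling. Higher genes made up 44.8% of those called in hippocampal cells and 57.3% in olfactory bulb cells, against 28.7% and 36.9% with median scaling and 66.4% and 25.4% with spike-in scaling, and 68.4% in hippocampal cells after centring. The median of all genes lay at -0.32 and 0.07, at -0.78 and -0.41 with median scaling and at 0.12 and -0.90 with spike-in scaling. List positions are relative to matched genes and so free of these shifts, except through bounds set to 0. Under at least 1 alternative, the p53, ensheathing, microglia, retinoic acid, BMP, stress and olfactory bulb patterning lists no longer stood apart in hippocampal cells, nor did the stem cell marker and mature neuron lists in olfactory bulb cells.

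The second comparison asked how olfactory bulb cells differed from hippocampal cells in the same state. Interferon-induced genes were lower in olfactory bulb cells. Oas1a, an antiviral enzyme gene, was lower by 7.19 in stem cells and by 1.90 in neurons, and Nqo1, a quinone reductase, by 4.29 and 1.89. In stem cells, 250 of 6023 genes were higher and 420 lower by 2-fold or more, and in neurons 536 of 7000 were higher and 560 lower. Both states shared 22 higher and 60 lower genes among 5911, where independent lists would share 13.0 and 24.3. A further 14 genes were higher in stem cells and lower in neurons (14.8 for independent lists) and 36 the other way (21.3). Across 5495 genes well above background on all arrays, the source differences in the 2 states had a Pearson r of only 0.116. The limma fit over the 4 arrays called 0 genes for source (smallest adjusted p 0.447), against 1384 higher and 864 lower for state. For source, 401 of 7112 genes had an unadjusted p under 0.05, not far above the number expected by chance. In simulations of the state term, the fit recovered 0% or 10% of differences of 2 log2 units. The 0 calls therefore do not show that the sources were alike. The calls for state also hold any difference between the slides.

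Of 15 interferon and antigen presentation genes measured in stem cells, 8 were lower and 0 higher, with a median of -1.73. In neurons 6 of 17 were lower and 0 higher, with a median of -0.84, and 4 were lower in both states. Irf7, a regulator of interferon genes, was lower by 3.38 and 1.89, Mx2 by 2.20 and 1.74 and Mx1 by at least 1.93 in stem cells and by 2.69 in neurons. Rsad2 (4.35 and 2.34), Oasl (3.52 and 2.16), Oas1i (4.49 and 1.85) and Ifi27l2b (3.66 and 1.77), which also belong to the interferon response, were among the leading lower genes. Further leading lower genes were Akr1b8, an aldo-keto reductase gene (6.30 and 1.78), the EGF receptor ligand gene Areg (3.52 and 3.36), Upp1 (2.49 and 1.81) and Lgals5 (1.82 and 1.98), and, as bounds, Cntn2 and Foxa3. Stress and unfolded protein response genes had medians of -0.71 and -0.08 (percentiles 0.94 and 47.7); Trib3 was lower by 2.42 and 1.57. Glycolysis and hypoxia genes had medians of -0.82 and -0.40 and stood apart in both states, with 0 of 21 higher and 4 lower in stem cells and 2 higher and 2 lower in neurons. Adm differed by -2.52 and -0.48, and the lactate transporter gene Slc16a3 by -0.54 and -1.38.

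The leading higher genes in olfactory bulb cells were Mdga2 (2.35 and 2.77), Septin10 (1.78 and 1.61), the vitamin E transport gene Ttpa (1.61 and 1.90), Igf1 (1.24 and 3.60) and the hyaluronan synthase gene Has2 (1.38 and 1.44). The transcription factor genes Zeb2 (1.93 and 1.29) and Nr2f2 (1.45 and 1.18), Abcd2, Akap5, Pde3b, Myo9a and Plcb4 completed the 12, and Cldn8 was higher as a bound. The 4 probes of Igf1 ranged from -0.85 to 1.24 in stem cells and from 0.37 to 3.60 in neurons. Dcx was higher by 2.28 in stem cells and differed by -0.70 in neurons, and Tubb3 was lower by 1.18 and 1.53. Ins1 differed by 0.22 and 0.32, Ins2 by -0.81 and 0.50, Pax6 by 0.19 and -0.74, Igfbp4 by -0.74 and 0.12, Mbp by -0.17 and -1.11, and Gfap by 0.73 in neurons. Pdx1 differed by -0.56 in stem cells and was higher by at least 0.26 in neurons, and Neurod1 was higher by at least 0.38 in stem cells.

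In stem cells, further lists stood apart. Neural stem and progenitor markers (0.05), proneural and neuroblast genes (0.14), hippocampal and cortical patterning genes (0.17) and cholesterol synthesis genes (-0.15) lay above matched genes. Of their 17, 14, 7 and 20 measured genes, 0, 3, 1 and 0 were higher and 1, 2, 1 and 0 lower by 2-fold or more. The median of all genes here was -0.43, so these positions alone do not mean higher levels in olfactory bulb stem cells. Pericyte, fibroblast and smooth muscle markers (-0.90) and ependymal and cilia genes (-1.10) lay below them, over 6 and 4 measured genes. In neurons, the list of olfactory ensheathing and Schwann cell markers had a median of 0.98, with 7 of 15 higher and 1 lower, and lay at -0.43 in stem cells (percentile 47.0). Ngfr, the low-affinity neurotrophin receptor gene, was higher by 4.95, Gfra3 by 4.71, Cdh19 by at least 3.24 and the neuropeptide gene Npy by 1.31.

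Also in neurons, retinoic acid genes (1.00), microglia and macrophage markers (0.88), astrocyte markers (0.73) and cholesterol synthesis genes (0.45) stood apart upwards. In stem cells the retinoic acid list lay at -0.48 (percentile 34.1), microglia and macrophage markers at -0.29 (55.7) and astrocyte markers at -0.29 (75.3). In neurons Rxrg, a retinoid receptor gene, was higher by 5.58, Aldh1a3 by 1.32, P2ry12, a receptor of microglia, by 2.43, C1qb by 1.36 and Ntsr2 by 1.66, while Cyp26b1 was lower by 1.74 and Cd44 by 1.25. Proneural and neuroblast genes had a median of -1.04 in neurons, with 7 of 14 lower and 2 higher; Dlx5 was lower by 3.32, Elavl3 by 2.68 and Elavl4 by 2.04. FGF and MAPK feedback genes had a median of -0.93 in neurons, with 8 of 16 lower and 0 higher, and -0.31 in stem cells (percentile 81.9). Fosl1 was lower by 3.35 and 1.15 and Dusp5 differed by -0.90 and -1.67. Immediate early genes had a median of -0.76 in neurons, with 7 of 22 lower and 0 higher, and -0.19 in stem cells (percentile 83.5); Egr4 was lower by 2.37 in stem cells and by at least 2.32 in neurons. Cell cycle inhibitors and p53 targets (-0.52), ribosomal proteins (-0.31) and insulin and beta cell genes (-0.54) also stood apart downwards in neurons, against -0.53 (percentile 37.2), -0.75 (5.46) and -0.40 (34.1) in stem cells. Of 22 insulin and beta cell genes measured in neurons, 7 were lower and 1 was higher; Scg2 was lower by 3.55, Foxa2 by 3.23 and Nkx6-1 by 3.28.

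**Figure D3:**
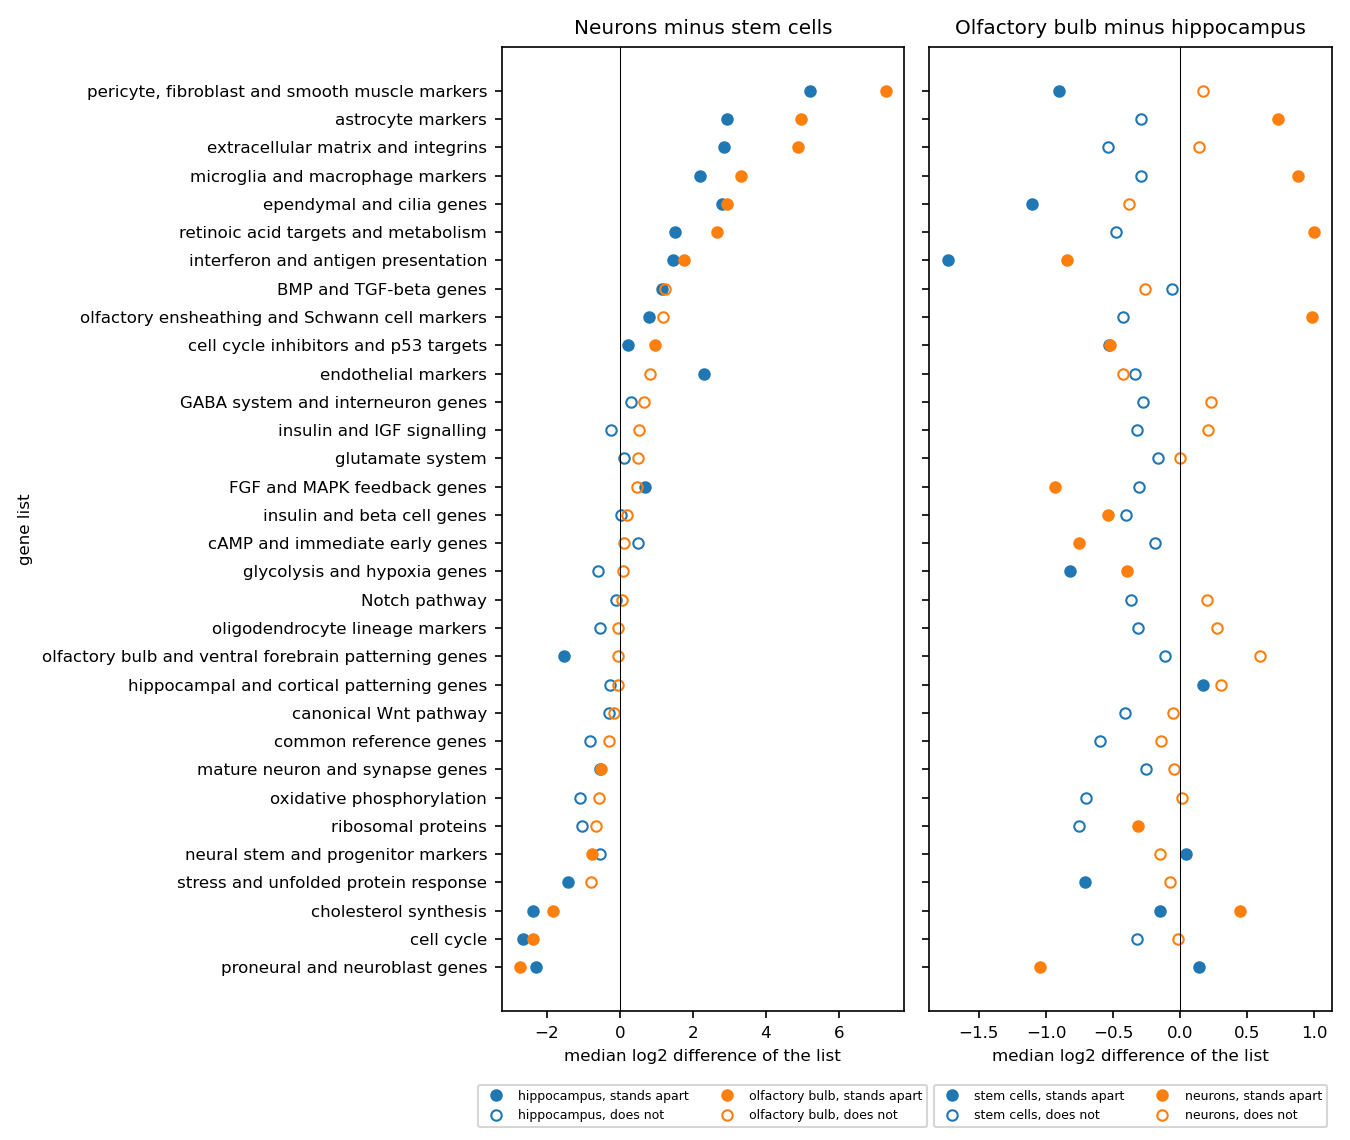
Median log2 difference of each of 32 gene lists, for neurons minus stem cells on the left and olfactory bulb minus hippocampus on the right; filled points lie in the lowest or highest 2.5% of expression-matched random lists. Pericyte, fibroblast and smooth muscle markers reach 5.22 and 7.29 on the left, and interferon genes lie at -1.73 and -0.84 on the right.

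Higher genes made up 37.3% of those called in stem cells and 48.9% in neurons, against 93.9% and 14.5% with spike-in scaling and 78.6% in stem cells after centring. The median of all genes moved from -0.43 and -0.01 to 0.42 and -0.62 with spike-in scaling, which turned the medians of the glycolysis and stress lists in stem cells and of the cholesterol list in both states to the other sign, and quantile normalization and centring also turned the cholesterol list in stem cells. With spike-in scaling, Septin10, Has2, Zeb2, Abcd2, Nr2f2, Akap5, Pde3b, Myo9a and Plcb4 (9 of the 12 leading higher genes) and Cldn8 fell short of 2-fold in neurons. Other named genes did too, among them Aldh1a3, C1qb and Npy in neurons. In stem cells this held for the lower genes Lgals5, Tubb3 and, as a bound, Cntn2. In stem cells the pericyte, ependymal, hippocampal patterning, glycolysis, stress and cholesterol lists, and in neurons the ribosomal list, no longer stood apart under at least 1 alternative.

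The last comparison asked where the change from stem cells to neurons differed between sources. The difference of changes was 2 log2 units or more for 140 genes in favour of the olfactory bulb and for 87 in favour of the hippocampus. These numbers were 26 and 729 with spike-in scaling and 91 and 141 after centring, so which source had more rests on the scaling. L1cam, a neural cell adhesion gene, was higher in neurons by 7.15 in olfactory bulb cells and differed by 0.23 in hippocampal cells, a difference of 6.92. Entpd2, an ectonucleotidase gene, followed with 6.62, the glutathione transferase gene Gsta1 with 6.12, Npy with 5.86, Rxrg with 5.77 and Tppp3 with 5.75. In the other direction, Cyp24a1, which degrades vitamin D, had a difference of -6.35, the endocytic receptor gene Lrp2 of -5.36, Apold1 of -4.74, the homeobox gene Cdx2 of -4.74, Opcml of -4.69 and Cnmd of -4.52. Gsta1 was 63.9-fold lower in olfactory bulb than in hippocampal stem cells and differed by 0.12 in neurons. With 1 array per group these differences have no residual to test them against.

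The remaining lists did not stand apart except where stated. Medians of neurons minus stem cells were -0.30 and -0.17 for the canonical Wnt pathway, -0.11 and 0.05 for the Notch pathway, 0.11 and 0.49 for the glutamate system, 0.31 and 0.66 for the GABA system, -0.55 and -0.04 for oligodendrocyte lineage markers, -0.60 and 0.09 for glycolysis and hypoxia genes, and 0.48 and 0.11 for immediate early genes. They were -1.10 and -0.57 for oxidative phosphorylation, -1.04 and -0.65 for ribosomal proteins, -0.82 and -0.31 for common reference genes, and -0.28 and -0.06 for hippocampal and cortical patterning genes. Olfactory bulb and ventral forebrain patterning genes had medians of -1.54, which stood apart, and -0.05, and the homeobox list of caudal identity had fewer than 3 measured genes. For olfactory bulb minus hippocampus, the medians were -0.41 and -0.05 for the Wnt pathway, -0.37 and 0.20 for the Notch pathway, -0.17 and 0.00 for the glutamate system, -0.28 and 0.23 for the GABA system, -0.32 and 0.27 for oligodendrocyte markers, and -0.32 and 0.21 for insulin and IGF signalling. They were -0.70 and 0.01 for oxidative phosphorylation, -0.60 and -0.14 for reference genes, -0.34 and -0.43 for endothelial markers, -0.32 and -0.01 for the cell cycle, -0.25 and -0.05 for mature neuron genes, and -0.06 and -0.26 for BMP and TGF-beta genes. They were -0.54 and 0.14 for extracellular matrix genes and -0.11 and 0.59 for olfactory bulb patterning genes, and in neurons they were -0.15 for stem cell markers, 0.30 for hippocampal patterning genes, 0.17 for pericyte markers and -0.38 for ependymal genes.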

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

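The genes in this part were singled out because they differed by 2-fold or more in opposite directions in the 2 cell sources or in the 2 cell states, on 1 array per group, and these differences were not tested. The search ran over the named genes; which list members were named was decided after their values were seen, with Atf3, Ndrg1, Hmox1 and Zic1 added last, so the numbers of genes found here depend on that choice. Spike-in scaling and centring on the median gene were also chosen only after the result was seen.

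Between neurons and stem cells, 6 named genes went opposite ways in hippocampal and olfactory bulb cells. Atf3, a stress-induced transcription factor gene, was lower by 2.53 in hippocampal neurons and higher by 3.15 in olfactory bulb neurons, a difference of 5.68. Cdh19, a cadherin gene of glia, was lower by at least 1.25 and higher by 1.14, a difference of at least 2.38. Ndrg1 was lower by 1.84 and higher by 1.23, a difference of 3.08. Cyp24a1 was higher by 2.34 and lower by 4.01, a difference of -6.35. Cnmd was higher by 2.71 and lower by 1.81, a difference of -4.52. Ocln, a tight junction gene, was higher by 2.31 and lower by 1.78, a difference of -4.09. Cdh19 fell short of 2-fold in at least 1 source under all 5 other scalings, Ndrg1 under median scaling (0.70 in olfactory bulb cells) and spike-in scaling (0.20), and Cnmd and Cyp24a1 under normexp.

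Between olfactory bulb and hippocampus, 12 named genes went opposite ways in stem cells and neurons. Npy was lower by 4.55 in olfactory bulb stem cells and higher by 1.31 in olfactory bulb neurons, a difference of 5.86. Tppp3 was lower by 2.30 and higher by 3.46, a difference of 5.75, and Atf3 was lower by 1.52 and higher by 4.15, a difference of 5.68. Agt differed by -1.01 and 2.06 (difference 3.07), Ndrg1 by -2.01 and 1.06 (3.08), Hmox1 by -1.87 and 1.07 (2.94), Zic1 by -1.56 and 1.30 (2.86) and Igfbp2 by -1.33 and 1.45 (2.78). Each of these last 5 fell short of 2-fold in at least 1 state under spike-in scaling, as did Npy and Atf3. Under normexp this held for Agt, Ndrg1, Zic1 and Cyp24a1, under median scaling for Hmox1 and Ndrg1, and after centring for Agt and Igfbp2. In the other direction, the neuronal RNA-binding protein genes Elavl3 and Elavl4 were higher in olfactory bulb stem cells by 1.19 and 1.70 and lower in neurons by 2.68 and 2.04, differences of -3.87 and -3.75. Opcml was higher by 1.94 and lower by 2.76, a difference of -4.69, and Cyp24a1 was higher by 2.07 and lower by 4.28, a difference of -6.35.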

How the results depend on the processing

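Spike-in scaling and centring on the median gene were chosen only after the results were seen; the other alternatives were planned. Quantile normalization, the mean over a gene's probes and the authors' table left all 14 counts within 1.5 times, the last by construction. Counts below are higher then lower genes where a pair is given. With normexp, 133 and 208 genes were called between sources in stem cells, 343 and 334 in neurons and 7 and 31 in both states. By the difference of changes, 86 and 47 were called (olfactory bulb, then hippocampus). The normexp offset of 50 pulls differences of dim genes towards 0 by construction, and median probe signals were 34.8 to 79.3. Whether this explains the whole fall was not tested. Without the filter on dim probes, 376 and 726 were called in stem cells, 812 higher in neurons, 52 and 99 in both states, and 529 and 267 by the difference of changes, over more genes by construction. With only genes well above background on all 4 arrays, fewer genes were compared, and 788 were higher in hippocampal neurons than stem cells, 1069 in olfactory bulb neurons, 634 in both, and 257 and 302 between sources in neurons. Median scaling gave 2856 lower genes in hippocampal neurons, 2363 in olfactory bulb neurons and 1959 in both. Spike-in scaling gave 976 lower in hippocampal neurons, 1125 and 3308 in olfactory bulb neurons, 1112 and 72 between sources in stem cells, 257 and 1516 in neurons, 33 lower in both states, and 26 and 729 by the difference of changes. Centring gave 915 lower in hippocampal neurons, 725 lower in both sources, 519 and 141 between sources in stem cells, 52 and 38 in both states, and 91 and 141 by the difference of changes. Apart from bounds set to 0, these 3 scalings shift all genes of a comparison alike, which moves counts by construction. The additive limma fit called 0 higher and 0 lower genes between sources (401 at an unadjusted p under 0.05). In simulations of the state term it recovered 0% or 10% of differences of 2 log2 units, so its power for such differences is low. Whether that alone explains the 0 was not tested. Of 377 values of named genes, 0 changed sign under the alternatives where 2-fold was called, and 33 lost the 2-fold call with spike-in scaling, 30 with normexp, 11 with median scaling, 7 with quantile normalization, 6 with centring and 3 with the mean over probes. Constant shifts can move list positions only through bounds set to 0, so the 128 of 128 list results unchanged under them say little about stability. Quantile normalization left 117 unchanged in whether they stood apart, normexp and the mean over probes 121 each, no filter 122, genes on all 4 arrays 119 and unmatched random lists 115. The others gained or lost that standing, except 1 that was reversed over genes on all 4 arrays. The olfactory bulb patterning list in hippocampal cells, with a median of -1.54, came to -0.012 over genes well above background on all 4 arrays and then lay above the middle of the random lists; fewer of its genes were left. Pairing by replicate was not possible because each group held 1 array. The additive limma fit compares the states with source as a term, and so pairs them by source, and the sources with state as a term. Signal over background limits the genes that were dim on the stem cell arrays, whose differences are bounds.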

Other observations

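Of the tests in this part, those on the further lists of Nrf2 targets and glia genes and on the percentile of Ins1 and Ins2 among genes of like signal were stated before their results were seen, and the tests of scaling, exchanged labels, other cells, microglia, arrays or pools per group, insulin signal over background on the stem cell and neuron arrays, and the medians and percentiles of the further lists under other scalings were chosen only after the result was seen.

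Nqo1, Akr1b8 and Gsta1, known targets of the oxidative stress regulator Nrf2, were lower in olfactory bulb than in hippocampal stem cells, and a further list of 28 Nrf2 target genes was tested. Of 22 measured, 8 were lower, 0 higher and 14 within 2-fold, with a median of -0.74 at percentile 0.32 of matched random lists, 0.27 log2 units below matched genes. The median was -0.30 or lower under 5 of 6 scalings and 0.11 with spike-in scaling, which left 1 gene higher, 1 lower and 20 within 2-fold. Spike-in scaling shifts genes alike, so it can move the percentile only through bounds set to 0. With normexp and quantile normalization the percentile was at most 0.77. The ferritin gene Fth1 was lower by 1.67, Gstp1 by 1.24 and Osgin1 by 3.21, while Gclm differed by 0.67, Gclc by -0.16 and Me1 by -0.13. These genes were chosen after their values were seen, and the values hold with the scaling used. Lower activity of this target set in the olfactory bulb stem cell pool is a candidate explanation of its place below matched genes, while the sign of the median itself rests on the choice of scaling. Of the list, 3 genes belong to a list fixed earlier and 21 were well above background on both stem cell arrays. In neurons the list lay at -0.01 (percentile 82.3).

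A further list of 20 genes of Schwann and ensheathing glia, of which 1 is in a list fixed earlier, had a median of 0.42 for olfactory bulb minus hippocampal neurons, at percentile 99.48. Its 14 measured members were mixed, with 5 higher, 3 lower and 6 within 2-fold; Ednrb was higher by 3.06 and Cryab, with a log2 signal 5.19 above the 75th percentile on the olfactory bulb neuron array, by 1.47, while Aqp1 was lower by 2.20, genes chosen after their values were seen. The median was 0.33 or higher under 5 of 6 scalings and -0.19 with spike-in scaling, which left 2 higher, 4 lower and 8 within 2-fold; with normexp and quantile normalization the percentile was at least 99.47. Of the list, 10 genes were well above background on both stem cell arrays. Whether glia of this kind were in the olfactory bulb neuron culture stays open, and the labels name no sort that would remove such cells.

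On the arrays labelled neurons, stromal, astrocyte and microglia markers were higher and neuroblast genes lower, while mature neuron and oligodendrocyte genes went both ways. The values argue against scaling as the cause of 2 parts: over 6 scalings and both sources the stromal median was at least 3.27 and the neuroblast median at most -1.78, but the mature neuron median came as near to 0 as -0.048, so that part cannot be told apart from scaling. Exchanged labels would put the cell cycle list higher on the neuron arrays, and it lay 2.07 below matched genes (-2.07) in the source nearer to 0. Cells of another type may contribute, but the test of this could not decide. Its result, 100% of the 15 measured stromal markers higher in both sources, restates the pattern. On the neuron arrays Col1a2 lay at 7.69 and 7.86 and Fn1 at 7.56 and 6.40 above the 75th percentile. Of the 20 listed genes, 6 are in another list and 6 were well above background on both stem cell arrays, and no sort is named. A change of the cells themselves, or a difference between the slides, stays open with 1 array per group.

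Interferon genes were lower in olfactory bulb cells in both states. Scaling alone would have to bring the list median to 0, and over 6 scalings it came no nearer than -0.79. Fewer microglia or macrophages would lower their markers too, but in olfactory bulb neurons these lay 0.78 above matched genes, and in stem cells 0.04 above them over 7 measured genes; 1 of the 18 listed markers is in another list. A property of the source stays possible and untested, with 1 pool per group, as does a chance difference between the pools.

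Ins1 and Ins2 were higher on both neuron arrays. Among the 200 genes nearest in stem cell signal, their changes lay at percentiles of 73.0 to 82.0, so changes of this size were common at such signals. This was the outcome stated beforehand for a signal close to background, so that explanation of the changes stays open. These neighbours include genes with real differences, and the comparison has little power. In a test chosen afterwards, the neuron signal was at least 8.32 times the lowest signal well above background for both genes. Background alone is therefore no likely source of the neuron signal, though that lowest signal is a minimum over the probes of an array. The low stem cell signal of Ins2, at 1.79 times against 7.35 for Ins1, leaves the size of its difference imprecise. Scaling kept both genes positive, with a smallest change of 0.39, and kept Ins2 in olfactory bulb cells at 1.45 or more, but leaves open whether Ins1, and Ins2 in hippocampal cells, reached 2-fold. Differentiation of the cells, other cell types in the cultures, a difference between the slides and cross-binding between the near-identical genes were not tested.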
